A study of Homo sapiens with 12 samples.

How the data were processed

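RNA sequencing of total RNA from 12 samples of HL60 cells was analysed, 3 in each of 4 groups: EV vehicle, EV doxycycline, TFEB vehicle and TFEB doxycycline. Per the labels' protocols the cells grew in RPMI-1640 with fetal bovine serum, RNA was isolated with a NucleoSpin kit and libraries were made with a NuGEN Ovation FFPE kit. Doxycycline was given at 1 µg/ml for 48 h, per the labels' protocols, which list this for each sample, vehicle samples included. Which samples received it was taken from the titles and the treatment given in the labels, and no marker in the EV line checks it. The replicates were biologically independent experiments, per the series description. Per the submitters' processing notes, STAR 2.5.3a and HTSeq 0.6.1 were used. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Antisense genes and genes with near-identical copies are therefore uncertain.

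The deposited file holds 1 normalized signal value per gene and library. That the authors divided read numbers by 1 factor per library was read from the values: within each library every value was a whole multiple of 1 step (100% of values at a tolerance of 0.01), with steps from 0.803 to 1.22. Whole reads were recovered by dividing by the step. In EV vehicle replicate 2 and TFEB vehicle replicate 3 the step lay within 1% of 1, where recovery cannot be told from rounding. In 12 of 12 libraries the product of the step and a median-ratio size factor computed on the recovered reads was 1. The libraries held 4474007 to 22488047 recovered reads. Between replicates the spread exceeded counting error, with chi-square per degree of freedom of 10.4 to 35.3 over 12 replicate pairs. This value is pooled over genes, so it does not show which error sets the precision of genes with few reads.

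Of 57820 genes in the file, the 23128 with a mean value of at least 10 over the 12 samples were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3. The fit had 1 mean per group, empirical Bayes moderation with a variance trend, two-sided tests and a Benjamini-Hochberg adjusted p threshold of 0.05. The values are not raw counts, so a test on normalized values was the main one. The comparisons were TFEB doxycycline against TFEB vehicle, EV doxycycline, EV vehicle and the mean of these 3, EV doxycycline against EV vehicle, TFEB vehicle against EV vehicle, the interaction of vector and doxycycline, and the genes called in 1 direction against each of the 3 controls. The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule named TFEB first and IDH1, IDH2, TET2, MYC, CEBPA, SPI1, TFE3 and MITF whatever their result. It added the 12 largest rises and the 12 largest falls in TFEB doxycycline against TFEB vehicle among genes with a mean of at least 50 called in 1 direction against each control. It further named up to 4 called members of each list with the largest change, or the 2 with the highest mean where fewer than 2 were called, and the 6 largest rises and falls among called genes with a mean of at least 50 for EV doxycycline and for TFEB vehicle against EV vehicle. Rankings were shortened from the bottom, and 3 genes higher in them are not named.

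The 27 gene lists (628 members, 627 found in the file by symbol or older symbol) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Members were counted with p adjusted over all genes and over the list alone. Standard errors are those of the limma fit. A call is said to stand under each scaling where it had the same direction on the deposited scale and after scaling to TMM factors, equal totals, equal upper quartiles and the median ratio of the 7290 nuclear genes with a mean of at least 200. The last scaling was chosen after seeing the data, since the deposited factors rest largely on genes near background and the level of expressed genes differed between libraries.

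Alternatives were other pseudocounts, filters and scalings, a fit without the variance trend, a fit of the compared groups alone, a replicate block, a minimum fold of 2, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. The procedure was tested on simulated data for TFEB doxycycline against TFEB vehicle (23128 genes), where limma recovered 9% of 2-fold and 73% of 4-fold changes with 6 false calls and edgeR 8% and 74% with 3. No positions were computed, and no column of the file was left out.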

Results

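RNA sequencing was read from 12 libraries of HL60, a human acute myeloid leukaemia cell line of promyelocytic character. The cells carried either an empty vector (EV) or a vector that expresses the S211A form of TFEB, a transcription factor of lysosomal genes, when doxycycline is added. Each line was sampled with vehicle and with doxycycline (1 µg/ml, 48 h), which gave 4 groups of 3 biologically independent replicates. The reads recovered per library ranged from 4474007 in EV doxycycline replicate 3 to 22488047 in EV vehicle replicate 2. On the deposited normalized scale the totals of these libraries, again the lowest and the highest, were 4012762 and 22302095, a ratio of 5.56. The totals averaged 15334982 ± 6212313 in EV vehicle, 7097589 ± 2961633 in EV doxycycline, 10177527 ± 2720457 in TFEB vehicle and 18181834 ± 3209461 in TFEB doxycycline (SD, n = 3 each). Mitochondrial genes took 23.8 ± 2.77%, 30.4 ± 3.70%, 26.6 ± 2.82% and 16.0 ± 2.38% of the reads of these groups (SD, n = 3). Nuclear genes with a mean under 200 took between 4.74% and 18.2% of a library. The genome build is not given in the sources used here, so genes are named by the symbols of the file and no positions are given.

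**Figure D1:**
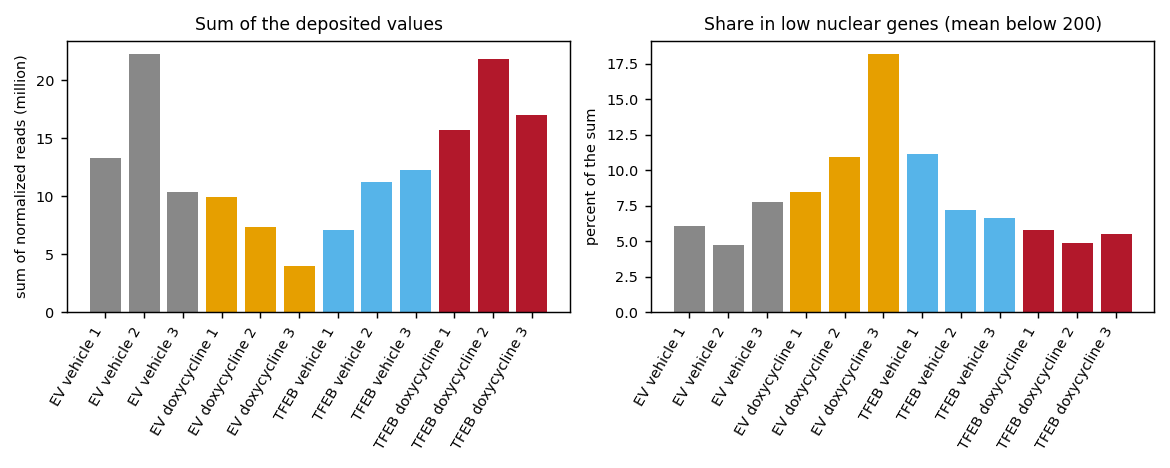
Sum of the normalized values (left) and percent of that sum in nuclear genes with a mean value under 200 (right), with 1 bar per library, coloured by group (3 libraries each). The sums ran from 4012762 to 22302095 and the shares from 4.74% to 18.2%, highest in EV doxycycline replicate 3.

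TFEB itself (ENSG00000112561.13) set the TFEB doxycycline libraries apart, as labelled, while its values overlapped among the 3 control groups. Its normalized value lay between 79.8 and 196 in the 9 libraries of the 3 control groups and between 14470 and 22629 in the 3 TFEB doxycycline libraries. The group means were 145 ± 45.3 in EV vehicle, 96.7 ± 25.9 in EV doxycycline, 124 ± 22.6 in TFEB vehicle and 18189 ± 4127 in TFEB doxycycline (SD, n = 3). The rise with doxycycline in the TFEB line was 7.18 on the log2 scale (SE 0.44, limma adjusted p = 3.14e-17). Reads of the transgene and of the endogenous gene cannot be separated in these values. TFE3 and MITF, relatives of TFEB, were not called in this contrast, with log2 changes of 1.19 (SE 0.45, limma adjusted p = 0.05) and 0.83 (SE 0.33, limma adjusted p = 0.0602).

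The comparison of TFEB doxycycline with TFEB vehicle asked what induction of TFEB S211A changed within its own line, with the drug present only in the induced cells. Genes of the lysosome rose. All 16 tested subunits and accessory proteins of the vacuolar proton pump (V-ATPase), which acidifies the lysosome, rose, and all 16 did so under each of 5 scalings of the libraries and when adjusted over the list alone. ATP6V0D2 went from 15.7 ± 7.15 to 7444 ± 1126 normalized reads, ATP6V1D from 50.8 ± 15.1 to 1431 ± 244 and ATP6V1H from 122 ± 32.3 to 3014 ± 796 (SD, n = 3). Of 43 lysosomal hydrolases, 28 rose and 0 fell, 27 under each scaling and 28 when adjusted over the list alone. Among them were the ganglioside activator GM2A, which rose by 6.62 on the log2 scale (SE 0.56, limma adjusted p = 5.2e-13), and the proteases cathepsin D (CTSD, by 6.29, SE 0.59) and cathepsin A (CTSA, by 5.13, SE 0.56). Of 26 lysosomal membrane proteins, 18 rose and 1, ABCA2, fell, with the same counts under each scaling and 21 and 2 when adjusted over the list alone. GPNMB rose by 8.41 (SE 0.42, limma adjusted p = 3.07e-20) and CD63 by 5.75 (SE 0.53, limma adjusted p = 8.31e-12). Of 35 autophagy genes, 21 rose and 0 fell, 20 under each scaling and 22 when adjusted over the list alone, led by the receptor OPTN (log2 rise 5.07) and WIPI1 (4.65). Of 25 genes of mTORC1 nutrient sensing, 13 rose and 3 fell, with the same counts under each scaling and over the list alone. FNIP2, a partner of folliculin, rose by 6.03, and the Rag GTPases RRAGC and RRAGD by 4.16 and 3.54. The competitive set test camera with its preset correlation called these 5 lists higher. With an estimated correlation it called none of them, with adjusted p = 0.328 for the V-ATPase list, adjusted p = 0.511 for hydrolases, membrane proteins and autophagy each, and adjusted p = 0.753 for nutrient sensing. Among the 7290 expressed nuclear genes alone the estimated-correlation test gave an adjusted p of 0.00583 for the V-ATPase list and 0.0168 for membrane proteins, and called none of hydrolases (0.268), autophagy (0.275) and nutrient sensing (0.28). With libraries scaled on expressed genes, 4 of 34 expressed hydrolases and 2 of 27 expressed autophagy genes fell. With doxycycline in the EV line 17 of 34 hydrolases, 7 of 18 membrane proteins and 10 of 27 autophagy genes rose on that scaling. Falls numbered 2, 1 and 1. On the deposited scale 1, 0 and 0 of all tested members rose there and 10, 7 and 3 fell. For autophagy the response to doxycycline was more positive in the TFEB line for 28 of 35 genes, 14 under each scaling. On expressed-gene scaling it was more positive for 13 of 27 and more negative for 4.

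**Figure D2:**
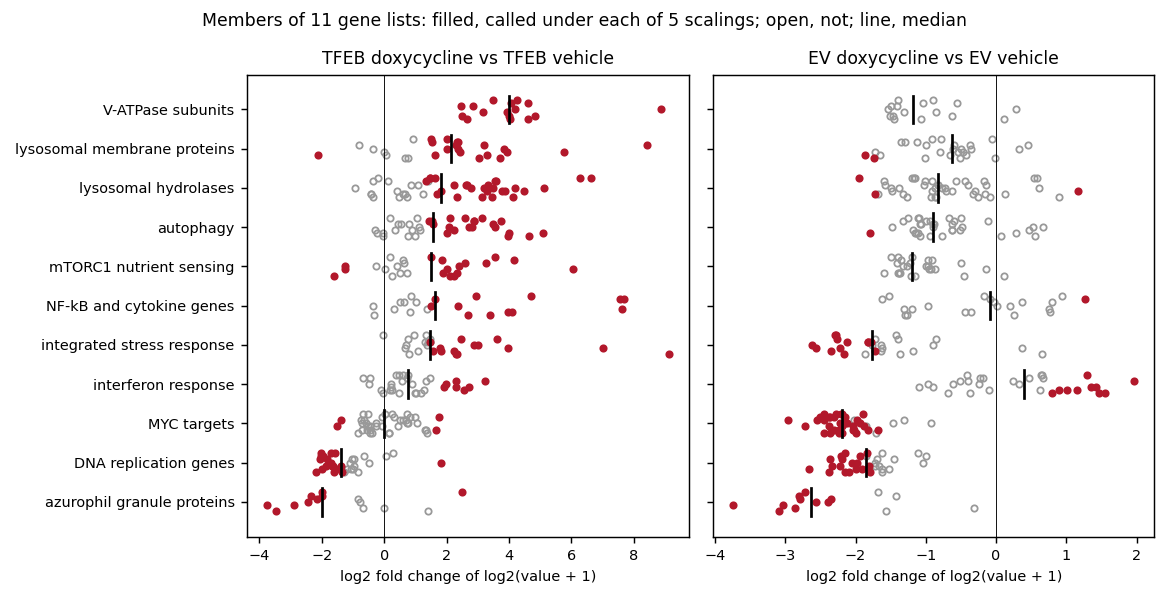
Change on the log2 scale of each tested member of 11 gene lists, with doxycycline in the TFEB line and in the EV line (n = 3 per group), with 1 point per gene, filled where the gene was called in the same direction under each of 5 scalings, and lines at the list medians. All 16 V-ATPase subunits lie above 0 in the TFEB line, from 2.46 to 8.87, and MYC targets lie below 0 in the EV line with a median of -2.19.

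Genes of the promyelocyte fell in the same contrast while parts of the macrophage program rose. The contrast does not separate TFEB from the drug. With doxycycline in the EV line 13 of 14 azurophil genes fell too, 10 under each scaling, as did 7 of 16 progenitor genes, 2 without EV vehicle replicate 2. In the TFEB line, 8 of 14 azurophil granule proteins fell and 1 rose, with the same counts under each scaling and 9 and 2 when adjusted over the list alone. PRTN3 fell from 3189 ± 1415 to 226 ± 59.5, myeloperoxidase (MPO) from 63170 ± 19654 to 5604 ± 973 and lysozyme (LYZ) from 3901 ± 618 to 547 ± 214 normalized reads (SD, n = 3), while the cystatin CST7 rose by 2.51 on the log2 scale (SE 0.57, limma adjusted p = 0.000748). Of 25 monocyte and macrophage genes, 8 rose and 4 fell, with the same counts under each scaling and 9 and 5 when adjusted over the list alone. EGR1 rose by 8.01, the scavenger receptor MARCO by 7.89 and the integrin ITGAX by 6.52, and the members that fell were CSF1R, IRF8, FCGR1A and CCR2. Of 25 mature granulocyte genes, 6 rose and 4 fell, 4 and 4 under each scaling and 6 and 7 when adjusted over the list alone. MNDA fell by 2.13; the median of this list was -0.304 and its mean 0.345. Of 20 myeloid transcription factors, 8 rose and 5 fell under each scaling and over the list alone, with rises of FOS (3.63), CEBPB (3.01) and JUN (2.48). Of 16 progenitor genes, 5 fell and 1 rose under each scaling and over the list alone. MYB fell by 2.79 and the receptor FLT3 by 2.02, and GATA2 rose by 3.52. Camera with its preset correlation called the azurophil and progenitor lists lower and the monocyte list higher. With an estimated correlation it gave adjusted p = 0.511, adjusted p = 0.328 and adjusted p = 0.511 for these lists. The granulocyte list had an adjusted p of 0.941 and the transcription factors an adjusted p of 0.112 in camera with the preset correlation. Leaving out 1 library moved some of these counts. The azurophil rises were 2 without EV vehicle replicate 2 or EV doxycycline replicate 1 or 3. Only 2 progenitor genes fell without TFEB vehicle replicate 2, TFEB vehicle replicate 3 or TFEB doxycycline replicate 1, and 3 without TFEB doxycycline replicate 3. Only 2 transcription factors fell without TFEB vehicle replicate 2 or TFEB doxycycline replicate 3, and 3 without TFEB vehicle replicate 3 or TFEB doxycycline replicate 1. Only 2 granulocyte genes fell without TFEB vehicle replicate 2 or TFEB doxycycline replicate 1 or 2.

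Genes of DNA replication fell in TFEB doxycycline against TFEB vehicle, as 30 of 31 did with doxycycline in the EV line, but 5 without EV vehicle replicate 2 and 18 without EV doxycycline replicate 3. Of 31 tested, 17 fell and 1, the histone mRNA binding gene SLBP, rose, with the same counts under each scaling and 20 and 1 when adjusted over the list alone. CDCA7 fell by 2.20 on the log2 scale (SE 0.52, limma adjusted p = 0.00127), GINS2 by 2.07, the helicase subunit MCM7 by 2.04 and PCNA by 2.03. The list was called lower by camera with the preset correlation, with adjusted p = 0.526 with an estimated correlation, and 11 members fell without TFEB vehicle replicate 3. The rise of SLBP was not called without TFEB vehicle replicate 1 or TFEB doxycycline replicate 2. Of 28 mitosis genes, only KIF20A fell, by 1.44 (SE 0.41, limma adjusted p = 0.0071), 1 when adjusted over the list alone, and its call ended without TFEB vehicle replicate 3 or TFEB doxycycline replicate 1 (adjusted p of 0.0561 and 0.0504); 3 members fell without EV doxycycline replicate 3, and 22 expressed members with libraries scaled on expressed genes. Camera called the mitosis list lower, with adjusted p = 0.753 with an estimated correlation. MKI67, a marker of cycling cells, had 8585 ± 2433 and 6627 ± 1608 normalized reads (SD, n = 3). The transcription factor MYC fell from 18740 ± 8676 to 5113 ± 1945 (SE 0.59, limma adjusted p = 0.0205), a call that held under each scaling but ended without TFEB vehicle replicate 2 or 3 or TFEB doxycycline replicate 1 or 3, with adjusted p between 0.0623 and 0.127. Of 40 MYC targets, 3 rose and 2 fell, 2 and 2 under each scaling and 0 and 1 when adjusted over the list alone, with an adjusted p of 0.463 in camera. Their median change of -0.01 on the deposited scale became -0.71 with libraries scaled on expressed genes, where 22 of 35 expressed targets fell. With 1 library left out, the rises among MYC targets numbered between 0 without TFEB vehicle replicate 1 or TFEB doxycycline replicate 2 and 6 without EV doxycycline replicate 3, with 1 without TFEB vehicle replicate 2 or TFEB doxycycline replicate 1 or 3. The falls numbered 1 without EV vehicle replicate 1, TFEB vehicle replicate 2 or 3 or any 1 of the 3 TFEB doxycycline replicates.

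Parts of the stress response, apoptosis, cytokine and interferon lists rose as well. Of 27 genes of the integrated stress response, 16 rose and 0 fell, 14 under each scaling and 19 when adjusted over the list alone. GDF15 went from 22.3 ± 12 to 12414 ± 4620, NUPR1 from 49.5 ± 16.8 to 6311 ± 1086 and DDIT3, which encodes CHOP, from 308 ± 94.1 to 4687 ± 370 normalized reads (SD, n = 3). Of 25 apoptosis regulators, 12 rose and 0 fell, 10 under each scaling and 15 when adjusted over the list alone. The cell cycle inhibitor CDKN1A rose by 7.46 on the log2 scale (SE 0.38, limma adjusted p = 9.67e-20), the survival genes BCL2A1 and BCL2L1 by 6.56 and 4.01, and the death gene BBC3 by 2.77. Of 21 genes of NF-kB and cytokines, 14 rose and 0 fell, 12 under each scaling and 15 when adjusted over the list alone. IER3 rose by 7.69, the chemokines IL8 and CCL3 by 7.61 and 7.57, and ICAM1 by 4.71. Of 30 interferon response genes, 12 rose and 0 fell, 7 under each scaling and 14 when adjusted over the list alone, with IFI6 up by 3.22 and IFIT3 by 2.71. With doxycycline in the EV line 10 interferon genes rose too, 10 under each scaling. Against EV doxycycline 8 were higher and 2 lower, 2 and 2 under each scaling. The interaction of vector and doxycycline was called for 8 of them, 1 under each scaling. Camera with its preset correlation called these 4 lists higher in TFEB doxycycline than in TFEB vehicle. With an estimated correlation it gave adjusted p = 0.526 for the stress response, adjusted p = 0.526 for apoptosis, adjusted p = 0.0931 for NF-kB and adjusted p = 0.605 for interferon. Of 19 unfolded protein response genes, 5 rose and 0 fell, 5 under each scaling and 5 when adjusted over the list alone, with SEC61B up by 2.48 and DNAJB9 by 2.25 and an adjusted p of 0.0572 in camera. This count was 2 without TFEB vehicle replicate 1 or TFEB doxycycline replicate 2, 3 without TFEB vehicle replicate 2 or TFEB doxycycline replicate 3, and 8 without EV doxycycline replicate 3. With libraries scaled on expressed genes, 4 of 16 expressed apoptosis genes, 3 of 19 unfolded protein response genes, 1 of 25 stress response genes and 2 of 7 interferon genes fell, the last 1 without TFEB vehicle replicate 3 or TFEB doxycycline replicate 1 or 2.

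Metabolic lists moved in part. IDH1, the cytosolic isocitrate dehydrogenase, rose from 330 ± 128 to 3239 ± 1421 normalized reads (SD, n = 3), a log2 change of 3.27 (SE 0.50, limma adjusted p = 1.47e-06) that held under each scaling. IDH2 had a change of -0.35 (SE 0.58, limma adjusted p = 0.711) and the DNA demethylation gene TET2 of 0.38 (SE 0.56, limma adjusted p = 0.677), and neither was called on the deposited scale; TET2 was called lower, by 0.48, with libraries scaled to equal totals. Of 15 isocitrate dehydrogenases and DNA methylation enzymes, 3 rose and 1 (UHRF1) fell, with the same counts under each scaling and over the list alone, and camera gave an adjusted p of 0.904. The rises were 1 without TFEB vehicle replicate 1 or 2 or TFEB doxycycline replicate 2 or 3, and the falls were 3 without EV doxycycline replicate 3 and 2 without EV vehicle replicate 2. Of 22 glycolysis genes, 7 rose and 0 fell, 7 under each scaling and 9 when adjusted over the list alone, among them ENO2 (4.39 on the log2 scale) and the glucose transporter SLC2A3 (3.97). Of 36 nuclear-encoded respiratory chain genes, 9 rose and 0 fell, 6 under each scaling and 12 when adjusted over the list alone, with the regulator PPARGC1A up by 4.19 and SDHB by 3.07. Camera with the preset correlation called both lists higher, with adjusted p = 0.753 for each with an estimated correlation. Of 24 cholesterol synthesis genes, 6 rose and 1 fell, 4 and 1 under each scaling and 6 and 1 over the list alone, with LSS up by 3.89 and an adjusted p of 0.498 in camera. Without TFEB vehicle replicate 1 or TFEB doxycycline replicate 2, only 3 respiratory chain genes and 2 cholesterol genes rose. Without TFEB doxycycline replicate 3 these counts were 5 and 3, and the cholesterol count was 3 without TFEB vehicle replicate 2. The 1 cholesterol gene that fell was not called without TFEB vehicle replicate 2 or TFEB doxycycline replicate 2 or 3. With libraries scaled on expressed genes, 6 of 17 expressed cholesterol genes rose and 8 fell, and their median turned from 0.259 over all members on the deposited scale to -0.354 (adjusted p = 0.852 in camera with an estimated correlation). On that scaling 5 of 31 expressed respiratory chain genes fell, as did 3 of 20 glycolysis genes, or 1 without TFEB vehicle replicate 2 or TFEB doxycycline replicate 2 or 3, and 3 of 11 isocitrate dehydrogenase and DNA methylation genes, or 5 without EV doxycycline replicate 3. On the deposited scale the respiratory chain rises numbered 14 without EV vehicle replicate 2 and 16 without EV doxycycline replicate 3. None of 13 mitochondrially encoded mRNAs was called by limma, adjusted over all genes or over the list alone; MT-CO1 had 409568 ± 122397 and 417499 ± 18844 normalized reads (SD, n = 3).

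Markers of other cell types were measured in the same contrast. Of 14 lymphoid markers, CD22, TRAC and NKG7 rose, by 7.72, 4.40 and 3.72 on the log2 scale, and CD79A and GNLY fell, with the same counts under each scaling and 3 and 4 when adjusted over the list alone. The median of this list was -0.342, its mean 0.716 and its adjusted p in camera 0.814. The falls numbered 0 without TFEB vehicle replicate 2 or TFEB doxycycline replicate 3, 1 without TFEB vehicle replicate 3 and 4 without TFEB doxycycline replicate 1. Of 7 erythroid markers, KLF1 fell by 1.16 (SE 0.41, limma adjusted p = 0.0339), as it did over the list alone, and its call ended without any 1 of the 3 TFEB vehicle replicates or TFEB doxycycline replicate 1 or 2 (adjusted p between 0.0522 and 0.139). None of 13 epithelial and fibroblast markers was called by limma, adjusted over all genes or over the list alone. Camera gave an adjusted p of 0.0721 for the erythroid and 0.215 for the epithelial and fibroblast markers. Of 9 abundant non-coding RNAs, a sign of RNA composition, NEAT1, RN7SL1 and RN7SL2 rose, 2 under each scaling and 3 when adjusted over the list alone, with a camera adjusted p of 0.0721. The call of RN7SL2 ended without TFEB vehicle replicate 1 or 3 or any 1 of the 3 TFEB doxycycline replicates (adjusted p between 0.0536 and 0.106).

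Among single genes called in the same direction against each of the 3 control groups, the largest rises after induction were those of DDX39BP2 (by 10.01 on the log2 scale), CD52 (9.18), GDF15 (9.11), TM4SF19 (9.04), AC006967.1 (9.01), the chemokine CCL18 (8.91) and ATP6V0D2 (8.87). CD52, a surface glycoprotein of leukocytes, went from 51.2 ± 33.9 to 26623 ± 4692 normalized reads (SE 0.46, limma adjusted p = 3.07e-20, n = 3). DDX39BP2 is annotated as a pseudogene, and reads shared with related genes make its value uncertain. The largest falls were those of the transcription factor NFE2, from 785 ± 248 to 67.2 ± 10.7 (SE 0.47, limma adjusted p = 1.1e-07, n = 3), TIFAB (by 2.80), PTPRCAP (by 2.79), the fucosyltransferase FUT7 (by 2.74), GAPT (by 2.71) and CXorf21 (by 2.65). CEBPA had 28.5 ± 13.4 and 58 ± 39 normalized reads and was not called (limma adjusted p = 0.171). SPI1, which encodes PU.1, had 2508 ± 720 and 3447 ± 899 and was not called (limma adjusted p = 0.605), and was called lower, by 0.39, with libraries scaled to equal totals. Of 23128 genes tested, 4032 were called higher and 1077 lower (limma, adjusted p under 0.05), and 2911 and 1032 of them in the same direction under each of the 5 scalings. The 1077 lower genes were 608, 651 and 655 without TFEB vehicle replicate 2, TFEB vehicle replicate 3 and TFEB doxycycline replicate 3, and the 1032 were 575, 617 and 546 without these and 570 without TFEB doxycycline replicate 2. Scaling the libraries to equal totals shifted changes by -0.842 (median over genes, as for the shifts given below) and gave 3066 higher and 6673 lower, so that most calls pointed down. Among expressed genes alone, scaled on themselves, 2636 were higher and 2587 lower. Camera called 12 of the 27 lists higher and 4 lower with its preset correlation and 0 with an estimated one, and fry called 15.

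**Figure D3:**
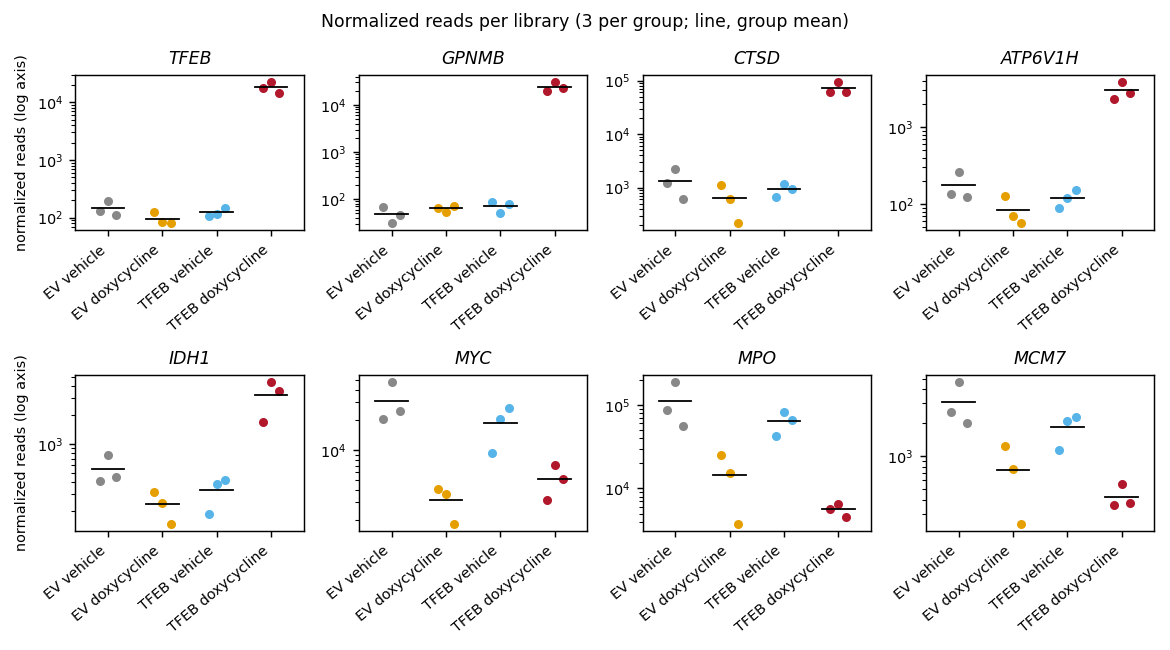
Normalized read values (log axis) of TFEB, GPNMB, CTSD, ATP6V1H, IDH1, MYC, MPO and MCM7 in each of the 12 libraries by group, with points for libraries and lines for group means (n = 3). TFEB lies between 14470 and 22629 in the TFEB doxycycline libraries and at or below 196 in all others.

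The same TFEB doxycycline libraries were set against the other control groups, as the design names 3 of them. The lysosomal genes CTSD and ATP6V1H and the gene IDH1 stood higher against these controls, CTSD by 7.08 on the log2 scale against EV doxycycline (SE 0.59) and by 5.91 against EV vehicle (SE 0.59), ATP6V1H by 5.20 and 4.15, and IDH1 by 3.74 and 2.52. NFE2 stood lower, by 2.34 against EV doxycycline and 4.08 against EV vehicle on the log2 scale. The azurophil gene MPO fell by 4.12 against EV vehicle (limma adjusted p = 9.52e-07) but differed by -1.03 from EV doxycycline without a call on the deposited scale (limma adjusted p = 0.199), and was called lower, by 2.40 (SE 0.29, limma adjusted p = 4.63e-06), with libraries scaled on expressed genes. On that scaling 8 of 12 expressed azurophil genes were lower than in EV doxycycline and 3 higher (adjusted p = 0.489 in camera with an estimated correlation). MYC fell by 2.58 against EV vehicle and was not called against EV doxycycline, with a change of 0.69 (limma adjusted p = 0.375) that turned to a called -0.75 with equal totals. Against EV doxycycline, all 16 V-ATPase subunits and all 27 integrated stress response genes rose, 16 and 20 of them under each scaling and 16 and 27 over the list alone, with adjusted p = 0.453 and adjusted p = 0.616 in camera with an estimated correlation. Of 9 abundant non-coding RNAs, a sign of RNA composition, 7 rose too, 3 under each scaling, with adjusted p = 0.616 in the same test. Against EV doxycycline 6282 genes were higher and 1242 lower, 3070 and 1238 of them under each scaling, and equal totals shifted changes by -1.41. The 1242 were 672 without EV doxycycline replicate 2 and 775 without TFEB doxycycline replicate 2, and the 1238 were 644 and 775. Against EV vehicle 2821 were higher and 1968 lower, 2275 and 1597 of them under each scaling, and equal totals shifted changes by -0.303. The 1968 were 1150 without EV vehicle replicate 2 and 1280 without TFEB doxycycline replicate 3, and the 1597 were 1022 and 984. In the same direction against each of the 3 controls, 2482 genes were higher and 313 lower, 1723 and 245 of them under each scaling. Independent lists would give 134 and 4.92, but the 3 comparisons share the TFEB doxycycline libraries, so this is no measure of chance. In 20 simulations without an effect the highest count was 0. They drew each gene on its own, without shifts of whole libraries, so they do not measure chance in these data either. The 313 were 191 without EV doxycycline replicate 2, 592 without EV doxycycline replicate 3, 196 without TFEB doxycycline replicate 3 and 1008 with edgeR, and the 245 were 528 without EV doxycycline replicate 3. Against the mean of the 3 controls 4914 genes were higher and 1843 lower, 3354 and 1689 of them under each scaling, with TFEB up by 7.23 and GDF15 by 9.37 and equal totals shifting changes by -0.852. The 1843 were 1118 without TFEB doxycycline replicate 3, and the 1689 were 1021 without it and 1068 without TFEB doxycycline replicate 2.

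Doxycycline in the empty vector line asked what the drug did without TFEB. Azurophil granule genes and MYC and its targets fell. MYC went from 31062 ± 14891 to 3178 ± 1176 normalized reads (SD, n = 3), a fall by 3.27 on the log2 scale (SE 0.59, limma adjusted p = 0.000717), and PRTN3 from 5742 ± 3992 to 453 ± 278 (SE 0.58, limma adjusted p = 0.000116). Of 40 MYC targets, 39 fell, 34 under each scaling and 39 when adjusted over the list alone, and of 14 azurophil genes 13 fell, 10 under each scaling and 13 over the list alone. Of 31 DNA replication genes 30 fell, 18 under each scaling and 31 over the list alone, and all 19 unfolded protein response genes fell, 13 under each scaling and 19 over the list alone. Of 27 integrated stress response genes 22 fell, 13 under each scaling and 25 over the list alone. Of 30 interferon response genes 10 rose, among them IFI6 (by 1.97) and IFIT3 (by 1.35), all 10 under each scaling and 10 over the list alone. Each of these 6 lists had adjusted p = 0.589 in camera with an estimated correlation. The largest rise was that of LOXL4, a lysyl oxidase, from 32.5 ± 1.6 to 713 ± 202 (SE 0.34, limma adjusted p = 1.24e-11), followed by the integrin ITGAM (by 1.99), IFI6 and complement C3 (by 1.95). SPI1 fell by 1.59 and IDH2 by 1.66, calls that ended without EV vehicle replicate 1 or 2 or EV doxycycline replicate 3, with largest adjusted p of 0.212 and 0.237, and for SPI1 also without EV doxycycline replicate 2, TFEB vehicle replicate 2 or TFEB doxycycline replicate 1 or 3. ORM1 fell by 3.64 and P2RY2 by 3.37. Of the 4 groups, EV doxycycline also had the lowest mean total and the highest mean mitochondrial share. In all, 783 genes were called higher and 5396 lower, 783 and 1330 of them under each scaling; equal totals shifted changes by 1.11 and gave 8224 higher and 1883 lower, and edgeR gave 3859 and 3372. Under each scaling, 72 and 149 were called without EV vehicle replicate 2, 178 and 671 without EV doxycycline replicate 3, 222 and 945 without EV doxycycline replicate 2, 498 and 872 without EV vehicle replicate 1, and 1635 and 1236 without EV vehicle replicate 3. The 5396 were 8149 without EV doxycycline replicate 1. The 6179 calls were 454 without EV vehicle replicate 2, 1766 without EV doxycycline replicate 3 and 3483 without EV doxycycline replicate 2; without the first, 15 MYC targets (median change -1.79 against -2.19 with it), 10 azurophil, 5 DNA replication, 3 stress response and 1 unfolded protein response gene fell and 6 interferon genes rose, and without the second, 36, 11, 18, 9 and 12 fell and 8 rose.

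With vehicle, the TFEB line was set against the EV line to ask whether the vector changed expression before induction. TFEB had 124 ± 22.6 and 145 ± 45.3 normalized reads in these groups (SD, n = 3), IDH1 330 ± 128 and 543 ± 193, and CTSD 932 ± 248 and 1348 ± 803. No gene was called by limma (smallest adjusted p = 0.452), with 1754 genes at an unadjusted p under 0.05, of which 1084 were higher and 670 lower. EdgeR and DESeq2 on the recovered reads also called 0, with 2754 and 2179 genes at an unadjusted p under 0.05 and smallest adjusted p of 0.409 and 0.338. Equal totals shifted changes by 0.542. Camera with its preset correlation called 1 list higher and 16 lower here although no member of any list was called, and 0 with an estimated correlation, and fry called 0.

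Whether doxycycline acted differently in the TFEB and EV lines was tested as the interaction of vector and doxycycline. The response of TFEB was 7.74 larger on the log2 scale in the TFEB line (SE 0.63, limma adjusted p = 6.7e-13), that of CTSD 7.46 larger, GPNMB 7.95 and IDH1 4.49 larger. The responses of LOXL4 and ITGAM were smaller in the TFEB line, with differences of -3.39 (SE 0.49, limma adjusted p = 7.28e-07) and -1.36 (SE 0.48, limma adjusted p = 0.0264). Azurophil genes fell in both lines. On the deposited scale the interaction was not called for PRTN3, MPO or LYZ (limma adjusted p = 0.997, 0.749 and 0.899) nor for MYC (0.164). With libraries scaled on expressed genes it was called for PRTN3, MPO and LYZ (limma adjusted p = 0.00038, 0.000302 and 0.00233) but not for MYC (0.105), and 8 of 12 expressed azurophil genes had a more negative response in the TFEB line and 2 a more positive response, with a median difference of -1.30. Of the lists, all 16 V-ATPase subunits had a more positive response in the TFEB line, 16 under each scaling and over the list alone. So had 27 of 27 integrated stress response genes, 20 under each scaling and 27 over the list alone. For lysosomal hydrolases the response was more positive for 29 of 43 and more negative for 1. These counts were 24 and 1 under each scaling and 29 and 1 over the list alone. With libraries scaled on expressed genes it was more positive for 22 of 34 expressed hydrolases and more negative for 7. The 1 more negative response on the deposited scale was not called without EV vehicle replicate 1 or 2, EV doxycycline replicate 2, TFEB vehicle replicate 1 or 2 or TFEB doxycycline replicate 2 or 3. Each of these 3 lists had adjusted p = 0.56 in camera with an estimated correlation. The interaction was called for 8177 genes, 6755 with the more positive response in the TFEB line and 1422 with the more negative, and 2497 and 1422 of them under each scaling; equal totals shifted the difference by -1.95 and gave 2608 and 13398, and edgeR gave 5230 and 5641. The 1422 were 815 without EV vehicle replicate 2, 896 without EV doxycycline replicate 2, 610 without TFEB vehicle replicate 1 and 803 without TFEB doxycycline replicate 2, with the same values under each scaling. Of 31 DNA replication genes 3 had a more positive and 0 a more negative response in the TFEB line (1 and 0 under each scaling, 3 and 0 over the list alone, adjusted p = 0.956 in camera; 5 and 0 without EV doxycycline replicate 1), whereas with libraries scaled on expressed genes the response was more negative for 24 of 27 expressed members and more positive for 1, and more negative for 22 of 23 expressed mitosis genes. Camera with an estimated correlation gave adjusted p = 0.491 for the azurophil and adjusted p = 0.32 for the DNA replication and mitosis lists each on that scaling. Of genes called under each scaling, 119 fell in both lines where independent lists would share 59.3, and 36 against 8.83 without EV vehicle replicate 2, which leaves 149 falls in the EV line. Rises in both lines numbered 61 against 98.6, 12 against 9.58 without that library and 48 against 25.6 without EV doxycycline replicate 3. A rise in the TFEB line with a fall in the EV line was shared by 226 against 167, but by 14 against 19.8 without EV vehicle replicate 2, 113 against 132 without TFEB vehicle replicate 1 and 105 against 110 without TFEB doxycycline replicate 2. A fall in the TFEB line with a rise in the EV line was shared by 15 against 34.9, but by 5 against 4.26 without EV vehicle replicate 2. Across the 7290 expressed genes, which are not independent replicates, the responses of both lines correlated with r = 0.452 and rho = 0.306.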

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

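Tests of the 2 patterns weighed here were chosen after the results were seen, except that of EV doxycycline replicate 3. The response to doxycycline differed between the TFEB and EV lines for 8177 genes in the interaction test, 3919 of them under each scaling. Among named genes the log2 response was more positive in the TFEB line for TFEB (7.74), IDH1 (4.49), ORM1 (3.96), PLD6 (6.40) and CTA-384D8.31 (6.66), under each scaling. It was more positive on the deposited scale, but not under each scaling, for CEBPA (2.75), SPI1 (2.07), TFE3 (1.73) and MITF (1.14). A more positive response can stem from a fall in the EV line alone. ORM1 had 517 to 988 normalized reads in EV vehicle and 32.3 to 100 in EV doxycycline. In the TFEB line it had 294 to 581 with vehicle and 497 to 553 with doxycycline. The response was more negative in the TFEB line, with differences of -3.39 for LOXL4 and -1.36 for ITGAM, under each scaling. CTA-384D8.31 is annotated as antisense, and its reads cannot be told from those of the other strand.

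The level of expressed genes differed between libraries on the deposited scale, by 6.87-fold in the median expressed gene against 1.34-fold in the median background gene. A candidate explanation is that scaling factors were set by genes near background: 79.4% of the 35430 genes behind the factors lie outside the expressed set, as this needs. Reads in background genes varied 1.54-fold between libraries, while reads in expressed genes varied 7.67-fold, as a fixed number of background reads per library needs. Whether doxycycline or TFEB changed the RNA per cell cannot be told apart from this. The totals are sums of reads scaled by 1 factor per library and hold no measure of the RNA amount per cell. The exact permutation test of the totals gave p = 0.1 in each line, the smallest value that 3 against 3 libraries allow, and cannot decide it either.

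MYC targets and azurophil granule genes were lower in EV doxycycline than in EV vehicle, as described for 39 of 40 and 13 of 14 genes. The lower level of expressed genes in these libraries is argued against as the whole cause, since with expressed-gene scaling the median change of the MYC targets was still -0.899 and 30 of 35 fell. Leaving out each of the 12 libraries on that scaling, 26 (without EV vehicle replicate 2) to 30 (without EV doxycycline replicate 3, for example) of these 30 still fell, as did all 10 azurophil genes, and on the deposited scale without EV vehicle replicate 2 the median MYC target change was -1.79 (median SE 0.53) against -2.19 (0.50), with 15 called against 39 but 38 of 40 lower at an unadjusted p under 0.05, so that 1 library is argued against as the whole cause. TFEB doxycycline cells in these samples are excluded as a cause, with a highest TFEB value of 0.696% of the TFEB doxycycline mean. The drug itself stays open as a hypothesis: 22 of 35 MYC targets fell and 5 rose with doxycycline in the TFEB line on expressed-gene scaling. On the deposited scale 2 of 40 fell and 3 rose. The response of MYC targets was more positive in the TFEB line for 24 of 40 and more negative for 0, or 11 and 0 under each scaling. With expressed-gene scaling it was more positive for 11 of 35 and more negative for 7. The drug and TFEB cannot be told apart in the TFEB line.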

How the results depend on the processing

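The results concern alternatives fixed in advance except the expressed-gene scaling, the calls under each scaling, the refits on expressed genes and the lists and overlaps without each library, which were chosen after seeing the data. Counts are ordered as TFEB doxycycline against TFEB vehicle, EV doxycycline and EV vehicle, then EV doxycycline against EV vehicle, the mean of 3 controls, the interaction, and the genes shared against each control. Equal totals gave 9739, 17381, 7890, 10107, 13477, 16006 and 6268 genes, equal upper quartiles 8540, 15250, 7510, 9581, 10749, 14818 and 5851, and expressed-gene scaling 8111, 16592, 7431, 11534, 10713, 15910 and 5888. Each of these scalings applies 1 factor per library, so the changes of genes shift together, though less where values are near the pseudocount of 1. Among expressed genes alone, EV doxycycline against EV vehicle gave 2564, the interaction 4349 and the shared genes 4301. Calls under each of 5 scalings numbered 4308 against EV doxycycline, 2113 for EV doxycycline against EV vehicle and 3919 for the interaction; without EV doxycycline replicate 3 these were 4183, 849 and 3601. For EV doxycycline against EV vehicle, no filter gave 3878 and a fit of its groups alone 2070; the cause was not tested. EdgeR gave 4692 shared genes against 2795, and 2196 lower genes against TFEB vehicle, 3798 against EV doxycycline and 4315 higher genes against EV vehicle; the cause was not tested. Pseudocounts of 0.5 and 5, a mean of at least 50, TMM factors, no variance trend, a 2-fold minimum and DESeq2 left each total within 1.5 times, but not each direction. A mean of at least 50 gave 647, 356, 1013, 220 and 196 lower genes against TFEB vehicle, against EV doxycycline, against the mean of controls, in the interaction and shared, and 243 higher for EV doxycycline against EV vehicle, where TMM factors gave 1542, no trend 459 and a 2-fold minimum 415. Lower genes numbered 2350 in the interaction with TMM factors, 910 there and 200 shared with no trend, and 756 against EV doxycycline and 1027 against the mean of controls with a 2-fold minimum. No filter gave 346 higher and 3532 lower genes for EV doxycycline against EV vehicle, and 826 lower in the interaction and 174 shared; fits of the groups compared alone gave 300 and 1770 for the first and 1803 lower against TFEB vehicle. Camera with an estimated correlation, which allows for correlated members, called 0 lists against 16 on the deposited scale. Among expressed genes alone, scaled on themselves, it called the V-ATPase list (adjusted p = 0.00583) and lysosomal membrane proteins (adjusted p = 0.0168). The 0 thus also depends on the scaling or the genes tested.

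Leaving out each library gave 3502 to 6383, 5294 to 8528, 3700 to 6018, 454 to 9221, 4669 to 7688, 5557 to 9866 and 2090 to 3467 genes in the same order, 0 to 0 for TFEB vehicle against EV vehicle and 14 to 17 lists. For EV doxycycline against EV vehicle the count was 454 without EV vehicle replicate 2, 1766 without EV doxycycline replicate 3 and 3483 without EV doxycycline replicate 2; a lone pair of samples is assumed to vary like the other groups. With the replicate number as a block the counts were 5824, 8301, 5462, 7927, 7452, 9176 and 3133 in the same order, 0 for TFEB vehicle against EV vehicle and 16 lists. Whether the numbers mark shared experiments is not given, and the data are mixed. Deviations of libraries with the same number correlated from -0.597 to 0.685 (12 of 18 pairs above 0.1), and among expressed genes from -0.225 to 0.72 (14 of 18). A library was closest to its own number in 19 of 36 comparisons, and in 24 of 36 among expressed genes, where 12 would be without pairing, a hint from the data and not from the design.

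Directions turned for 4 named genes, and the cause was the shift between scalings. With equal totals TET2 (-0.48) and SPI1 (-0.39) were called lower in TFEB doxycycline than in TFEB vehicle, and MYC (-0.75), IDH2 (-0.87) and TET2 (-0.92) lower than in EV doxycycline. Equal upper quartiles gave TET2 -0.63 against EV doxycycline. Expressed-gene scaling gave MYC -0.69, IDH2 -0.81 and TET2 -0.86 against EV doxycycline, the same values among expressed genes alone, and TET2 0.42 for EV doxycycline against EV vehicle; among expressed genes alone SPI1 was -0.28 in TFEB doxycycline against TFEB vehicle. Of 149 named results, 148 stood with a pseudocount of 5 and with TMM factors, 135 without a filter (14 lost their call), 146 with the block, 145 with edgeR and 143 with DESeq2. Small changes were rarely detectable on the deposited scale: in data simulated with its spread for TFEB doxycycline against TFEB vehicle, 9% of 2-fold changes were recovered. This rate does not carry over to expressed-gene scaling, where the changes of -0.28 for SPI1 and 0.42 for TET2 were called. Spread between replicates exceeded counting error, with chi-square per degree of freedom of 10.4 to 35.3, and depth itself was not varied.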

Other observations

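The tests on CD22, TRAC and NKG7 were chosen after their values were seen. CCL18, a macrophage chemokine, averaged 5653 ± 1776 normalized reads in TFEB doxycycline and 13.3 ± 6.43 in EV doxycycline (SD, n = 3), and SPINK1, a protease inhibitor, 6564 ± 2603 and 11.8 ± 1.49. PLD6 rose by 2.79 on the log2 scale with doxycycline in the TFEB line (SE 0.42) and fell by 3.61 in the EV line (SE 0.42), each under each scaling. STAP1 rose in both lines, by 1.98 and 1.89 (SE 0.33 each), with a limma adjusted p of 0.89 for the difference.

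Metabolic genes fell with doxycycline in the EV line on the deposited scale, where the median change of all expressed genes was -1.29. List medians were -1.73 for cholesterol synthesis, -1.74 for glycolysis, -1.38 for the respiratory chain and -1.24 for mitosis. On expressed-gene scaling they were -0.595, -0.467, -0.309 and 0.0422 in that order. There 8 of 17, 8 of 20, 7 of 31 and 0 of 23 expressed members fell and 1, 2, 1 and 1 rose. The respiratory chain and mitosis falls thus cannot be told from the shift of expressed genes as a whole. Of 24 cholesterol synthesis genes 19 fell, 10 under each scaling and 21 when adjusted over the list alone, of 22 glycolysis genes 15, 9 and 17, and of 36 respiratory chain genes 26, 8 and 30. Of 28 mitosis genes 12 fell, 0 under each scaling and 18 over the list alone. Camera with an estimated correlation gave adjusted p = 0.603 for mitosis and adjusted p = 0.589 for each of the others. Without EV vehicle replicate 2 the limma counts were 1 for cholesterol synthesis and 0 for the others; without EV doxycycline replicate 3 they were 8, 4, 1 and 0 in the order cholesterol synthesis, glycolysis, respiratory chain and mitosis. Without EV doxycycline replicate 2 only 3 mitosis, 14 respiratory chain and 10 glycolysis genes fell, and without EV vehicle replicate 1 8 mitosis and 15 respiratory chain genes; without EV doxycycline replicate 1 24 mitosis genes fell.

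CD22, TRAC and NKG7, found in lymphocytes, rose in TFEB doxycycline, where CD22 averaged 10348 ± 3097 against 47.8 ± 11.9 in TFEB vehicle (SD, n = 3). Lymphoid cells in the cultures are argued against, since 0 of 9 lineage-defining lymphoid markers were called higher, with a highest TFEB doxycycline mean of 40.8. Scaling is argued against, since the smallest of the 3 rises was still 2.87 with equal totals, the largest shift between scalings being 0.842. Background reads are argued against as well: they varied 1.54-fold between the 12 libraries, while the lowest TFEB doxycycline library held at least 3.76 times the reads of the highest other library in each of the 3 genes. The induced expression in the HL60 cells themselves remains a hypothesis.

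Other splits of the samples were refitted as tests planned in advance. For a comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The genes called numbered 5109 in the real split and at most 0 in the others for TFEB doxycycline against TFEB vehicle, 7524 and 0 against EV doxycycline, 4789 and 0 against EV vehicle, and 6179 and 52 for EV doxycycline against EV vehicle, so that 1 of 10 splits gave as many in each. For TFEB vehicle against EV vehicle 10 of 10 splits gave at least the real 0, and the highest other was 1. For gene lists 3 of 10 splits gave as many as the real 16, with up to 17 in another. In 100 splits of the 12 libraries, only the real one gave as many genes for the mean of the 3 controls (6757, highest other 515), for the interaction (8177, highest other 5455) and for genes shared against each control (2795, highest other 0). This argues against group labels without any effect. It does not exclude chance for single genes or for the size of a count. Splits that mix TFEB doxycycline libraries with others raise the spread within groups, and the splits ignored the replicate number.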
